A study of Drosophila melanogaster with 2 samples.

How the data were processed

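Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on whole adult male Drosophila melanogaster of a transgenic line that stably expresses the CG33017 protein fused at its C-terminus to green fluorescent protein (GFP). Per the labels' description of the samples, the precipitation used an antibody against GFP, while the antibody field of the labels names the target, CG33017. The description was followed here. Per the labels, chromatin was fragmented by sonication. The labels number the 2 samples as biological replicates 1 and 2 of 1 group, so there was no comparison between conditions. Samples of an untagged line were not analysed here.

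The values used were peak lists on the dm6 assembly. Per the text deposited with the samples, peaks were called by the authors on each replicate against 1 control alignment shared by both replicates, then on the pooled replicates against the same control, and a final list was derived by a threshold on the irreproducible discovery rate (IDR). The aligner, the peak caller, their versions and the IDR threshold are not given in the sources used here. Each deposited peak carries an interval, a summit, a signal value and a q-value as −log10. The signal is the authors' own value for that peak, and it was used here to rank peaks within a list. In a check on X, signals were multiplied by set factors before ranking. The deposited −log10 q-value sat at a single ceiling for the peaks of the IDR list and was not used for ranking. Each replicate list and the pooled list held 30000 peaks, and the IDR list held 4867. In 3114 of the 4867 IDR peaks (64.0%) the deposited summit was the midpoint of the interval. Taking peak midpoints as an alternative therefore changed nothing for those peaks. All 4867 IDR peaks were the 4867 highest-signal peaks of the pooled list. Equal list lengths show no depth, and the number of reads behind each list is unknown here, so the intervals below cover the counting of peaks only. Signal tracks were not used here.

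Summits were placed on the Ensembl release 115 annotation of BDGP6 and on the matching NCBI sequence, whose arm lengths fit dm6. Arms 2L, 2R, 3L, 3R, 4 and X were used, with 18164 genes after transposable elements were left out, of which 13945 were protein-coding. A summit within 500 bp of any annotated transcription start site (TSS) was called promoter-proximal, and a gene with such a summit at any of its TSSs was called bound. Each base was given to 1 of 6 classes in the order 5' UTR, coding sequence, 3' UTR, non-coding exon, intron and intergenic. Shares were compared with the share of bases by an exact two-sided binomial test, with exact 95% Clopper-Pearson intervals. The count of summits on X was tested in the same way against X's share of protein-coding TSSs. For 38 gene lists and for promoters with a TSS of another gene on the other strand within 500 bp upstream, bound genes were counted by two-sided Fisher's exact tests. For 19 consensus sequences, windows of 100 bp each side of promoter summits were compared with windows at the same offsets in unbound promoters matched over 10 groups of GC content. All 8-mers present in at least 20 windows of 50 bp each side of the summit were compared with flanks 300 to 500 bp away on 2L and 2R, and the best was tested on 3L, 3R, X and 4. P-values were adjusted by Benjamini-Hochberg within each family at a threshold of 0.05. These p-values set the list against random positions, genes or windows and do not measure variation between animals. Neighbouring genes can share a peak, so genes were not fully independent.

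The error of each share was taken from the replicates. The 4867 highest-signal peaks of each replicate's own list were analysed in the same way, and the mean ± SD over n = 2 is given beside the value of the IDR list. The tests, the gene lists, the consensus sequences, most alternatives and the rule for named genes were fixed before the data were examined, except the minimum of 20 windows for an 8-mer, which was set afterwards. The rule takes the gene with the TSS nearest to each of the 25 IDR peaks of highest signal, CG33017 itself, up to 4 members with the highest signal in each list that passed its test, and the 3 IDR peaks whose ranks differed most between replicates. Of the genes this rule takes, 1 is not reported here. Other genes named were chosen after their values were seen, and the text says so.

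The alternatives were the part of the IDR list with the higher signal, each replicate's own list, peaks without 111 that were mostly soft-masked, peak midpoints, windows of 250 and 1000 bp, protein-coding TSSs only, circular shifts, other backgrounds and other discovery arms. Assigning bound genes by the canonical TSS only, or by the nearest TSS only, and comparing 8-mers with no minimum number of windows, were chosen after seeing the data. The procedures were tested on simulated data. In 20 sets of 4867 uniformly placed summits the promoter share averaged 13.6%, 0 sets passed the promoter test, and 3 list calls arose over the 20 sets among 18164 genes. With summits added at 68 of 86 ribosomal protein promoters, 69 were found bound. An 8-mer planted in 494 of 4867 windows was ranked first. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9 were used.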

Results

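CG33017-bound chromatin was profiled in whole adult males carrying a GFP-tagged copy of the protein, in 2 biological replicates of 1 group. The peak lists show where in the genome the anti-GFP precipitate was enriched over the control, at which genes, and over what sequence. Samples of an untagged line were not analysed, so signal that does not come from the tagged protein was not separated. Binding below means presence in these peak lists. Read depth is unknown from the peak lists. The IDR list held 4867 peaks with a median width of 404 bp and signal values from 105.1 to 3404.

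The strongest CG33017 sites were shared by both replicates and lay mostly just upstream of genes. The highest peak (2L, 6612349 to 6612956, signal 3404) lay in an intron of CG11050, 1023 bp downstream of the nearest TSS, and ranked 1 in each replicate. Of the 25 strongest peaks, 20 had a summit within 500 bp of a TSS, and 19 of these lay upstream of it. Their lowest rank was 30 in replicate 1 and 27 in replicate 2. The next strongest sites were 86 bp upstream of CG14100 (3L, 19590435 to 19590809, signal 2981) and in an intron of CG11309 (3L, 21304359 to 21304807, signal 2869).

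Several of the other top sites lay at characterised genes. Gapdh2, a glycolytic enzyme gene, had an intergenic summit 163 bp upstream of its TSS (X, 15867769 to 15868204, signal 2415). Lpin, which encodes a phosphatidate phosphatase, had an intronic summit at an offset of -243 bp (2R, 8146011 to 8146456, signal 1990). The summit nearest to aay, a phosphoserine phosphatase gene, lay at -192 bp in an intron of Atat (3L, 9422836 to 9423256, signal 1984). Trl, which encodes the GAGA factor, held an intronic summit 1541 bp downstream of its nearest TSS (3L, 14759290 to 14759744, signal 2032). The summit nearest to cbt, a gene for a zinc finger transcription factor, lay 1385 bp away inside an intron of ush (2L, 480572 to 481353, signal 2766). Lk6, a protein kinase gene, held a summit in its own intron at -978 bp (3R, 11760836 to 11761435, signal 2128). The remaining peaks of the 25 were assigned to CG18549, CG1635, mRpL41, Fkbp14, Art3, CG5611, Ugalt, CenG1A, CG31668, CG18428, CG11357, papi, CG10165, Tcs5, CG1888 and Acsf2, with signals from 1832 to 2642. At 7 of the 25 sites a TSS of a second gene lay within 500 bp, such as mRpS10 beside Art3 and mRpS23 beside CenG1A.

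The CG33017 gene itself (FBgn0053017, 2R, 16272114 to 16277655) had no IDR summit within 500 bp of its TSS. The pooled list held a peak there (2R, 16271757 to 16272160, signal 96.2), with a summit at -155 bp and a rank of 5480 of 30000. The peak nearest to that TSS ranked 10012 in replicate 1 and 3217 in replicate 2.

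Replicates shared most of the IDR sites. Their equal-sized top lists overlapped 86.7% ± 0.421 (SD, n = 2) of the IDR peaks by at least 1 bp, and the 2 top lists overlapped each other at 75.7% of peaks. Across the 4859 IDR peaks with a peak in both full lists, Spearman's rho of the signal was 0.678 (permutation p = 1e-05, the smallest that 100000 permutations can give). This is a relation across peaks, which are not independent replicates. The largest rank differences were at peaks near chn (2R, 15128504 to 15128604), CG10543 (2R, 20997909 to 20998175) and hebe (2R, 9833570 to 9833824). These intronic peaks ranked 885, 1104 and 1158 in replicate 2, and no peak of replicate 1 overlapped them. Because the IDR list was made from both replicates, its overlap with each is not independent evidence of agreement.

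CG33017 summits concentrated at promoters. Of the 4867 summits, 2967 (61.0%, 95% interval 59.6 to 62.3%) lay within 500 bp of a TSS, where 13.6% of bases lie, a 4.50-fold excess (exact binomial p below 1e-300). The replicate top lists gave 60.4% ± 1.54 (SD, n = 2). Promoter summits had a median offset of -83 bp, with quartiles at -169 and 7.5 bp, and 72.8% lay upstream of the TSS. The other 1900 summits had a median distance of 1805 bp.

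**Figure D1:**
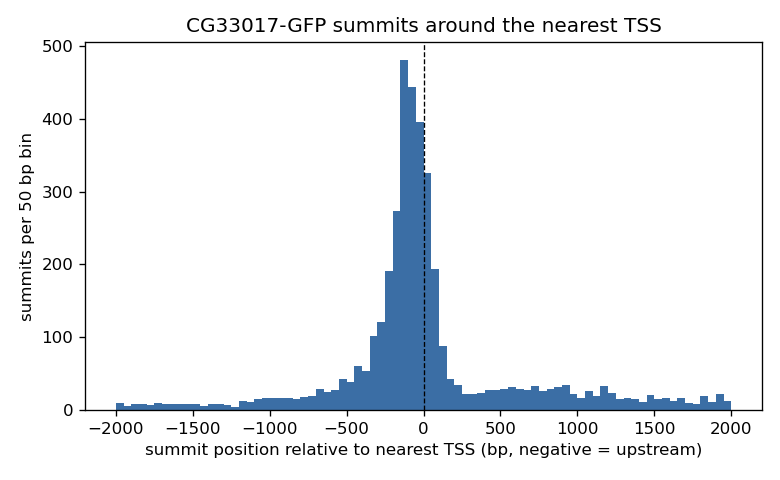
Number of IDR summits per 50 bp bin (y axis) against position relative to the nearest TSS in bp (x axis, negative values upstream). The bars peak just upstream of the dashed line at the TSS, where the median offset of promoter summits was -83 bp.

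Relative to their shares of bases, 5' UTRs held an excess of summits, and summits were nearly missing from coding sequence. The 5' UTR held 762 summits (15.7%), 4.64-fold more than its share of bases (exact adjusted p = 2.67e-267). Within the IDR list the 5' UTR share was 10.7% in the fifth with the highest signal and 19.8% in the fifth with the lowest. Coding sequence held 28 summits (0.575%, 95% interval 0.383 to 0.830%) against 16.7% of bases, 29.1-fold fewer. This held for the IDR list and much less for weaker peaks: the coding share was 7.25% in the 25133 other pooled peaks and 14.5% in the 3000 of lowest signal. The 3' UTR held 98 summits, 0.408 of its share of bases (exact adjusted p = 6.08e-26). Introns, with 2226 summits (45.7%), and intergenic sequence, with 1624 (33.4%), were 1.07-fold and 1.09-fold above their shares of bases (exact adjusted p = 1.76e-05 and 2.00e-05). Non-coding exons held 129 summits, a 1.51-fold excess. In the replicate top lists the coding share was 0.709% ± 0.0436 and the 5' UTR share 15.6% ± 0.160 (SD, n = 2). The intergenic excess was not called in the list of replicate 1, at 31.1%.

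The X chromosome carried fewer CG33017 sites than the large autosomal arms. X held 623 summits (12.8%, 95% interval 11.9 to 13.8%) against 17.0% of protein-coding TSSs (exact binomial p = 6.35e-16), which is 0.716 of the autosomal density. The replicate top lists gave a ratio of 0.725 ± 0.0589 (SD, n = 2). The deficit was smaller in longer lists: X held 15.5% of the other pooled peaks, 16.1% of all peaks of replicate 1 and 13.6% of all peaks of replicate 2. Arms 2L, 2R, 3L and 3R held between 25.3 and 27.6 summits per 100 protein-coding TSSs, and X held 19.0. Of protein-coding genes, 15.8% were bound on X and 25.9% on 3L. The small chromosome 4 held 15 summits, 0.418 of its share by TSSs.

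In all, 3631 genes were bound, including 3314 of 13945 protein-coding genes (23.8%). The replicate top lists gave 3574 ± 151.3 bound genes (SD, n = 2), and 2841 of the 3631 (78.2%) were bound in both. Of the 38 lists, 8 held more bound genes than other genes did, 10 held fewer, and 20 did not pass. A restriction to the higher-signal part of the IDR list left 2057 bound genes.

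Ribosomal protein genes stood out most. Of 86 cytoplasmic ribosomal protein genes, 69 were bound (80.2%; odds ratio 13.3, exact adjusted p = 4.44e-27), and the replicate top lists gave 80.8% ± 0.822 (SD, n = 2). Among the strongest were RpL34b (3R, signal 823.6), RpS27 (3R, signal 621.4) and RpL14 (3L, signal 465.6). Mitochondrial ribosomal protein genes were bound at 33 of 73 (45.2%; odds ratio 2.66, exact adjusted p = 0.000361). Their top members were mRpL41 (2R, signal 2325), mRpS10 (3R, signal 2098), mRpS23 (2L, signal 1974) and mRpL23 (3L, signal 1197). The mitochondrial list lost its call in the list of replicate 1 (24 of 73, exact adjusted p = 0.113), in the higher-signal part of the IDR list (odds ratio 1.65) and when a summit counted only for its nearest TSS, a choice made after seeing the data (odds ratio 1.11). Aminoacyl-tRNA synthetase genes were bound at 14 of 33 (exact adjusted p = 0.0458), with SerRS (signal 455.3), IleRS (signal 327.5), GluProRS (signal 240.5) and ThrRS (signal 239.6) highest, but did not pass in either replicate's own list (exact adjusted p = 0.241 and 0.168).

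Clock, Hippo pathway, insulator, Polycomb and Trithorax, and autophagy genes were also bound more often than other genes. Of 13 circadian clock genes, 8 were bound (odds ratio 5.14, exact adjusted p = 0.0127). They included cry, the blue-light receptor of the clock (signal 720.9), its negative regulator tim (signal 624.8), the transcription factor gene Pdp1 (signal 517.7) and the kinase gene sgg (signal 391.6). Of 13 Hippo pathway genes, 7 were bound (exact adjusted p = 0.0411), led by ex (signal 261.7), Mer (signal 253.9), the kinase gene hpo (signal 220.1) and kibra (signal 177.6). Of 17 insulator and promoter-binding factor genes, 9 were bound (exact adjusted p = 0.0255), led by Chro (signal 1562), Cp190 (signal 985.6), Dref (signal 459.3) and M1BP (signal 451.2). The ribosomal protein gene RpL13, named after its value was seen, carried the same signal as Dref, so 1 peak probably counted in both lists. Polycomb and Trithorax genes were bound at 10 of 20 (exact adjusted p = 0.0331), with ph-p (signal 1226), the chromatin remodeller gene brm (signal 1025), the histone methyltransferase gene E(z) (signal 849.3) and Sfmbt (signal 313.5) highest. Autophagy genes were also bound at 10 of 20 (exact adjusted p = 0.0331), led by Atg2 (signal 684.6), Atg17 (signal 423.2), Atg7 (signal 372.9) and Atg18a (signal 322.8). The clock call was lost at 250 bp from a TSS (odds ratio 3.47), and the Polycomb and Trithorax call at 250 and 1000 bp (odds ratios 1.74 and 2.70). The Hippo and insulator calls were lost in the list of replicate 1 (exact adjusted p = 0.188 and 0.0892). In the list of replicate 2 both passed (exact adjusted p = 0.00255 and 0.0215), so these calls differed between replicates. With the nearest TSS only, 2 of the 8 calls held, those of cytoplasmic ribosomal protein and clock genes. Under circular shifts along the gene order, which keep neighbouring genes together, 3 of the 8 calls held, those of both ribosomal protein lists and of the clock genes. There the permutation adjusted p was 0.0671 for Hippo, 0.0643 for insulator, 0.0643 for Polycomb and Trithorax, 0.0538 for autophagy and 0.0735 for tRNA synthetase genes.

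Chemoreceptor, cuticle, seminal fluid, germline, homeobox, antimicrobial peptide and histone genes were bound less often than other genes. Chromatin came from whole flies, so binding confined to a small share of cells may have been missed. This limit also covers the tissue lists below. None of 180 chemoreceptor genes (exact adjusted p = 1.03e-20) and none of 122 cuticle protein genes (exact adjusted p = 4.76e-14) had an IDR summit. Of 56 accessory gland and seminal fluid genes, 2 were bound, Sfp26Ad and Sfp33A3 (exact adjusted p = 0.000319). Testis and germline genes were bound at 5 of 64 (exact adjusted p = 0.00711), with piwi (signal 250.9), Mst36Fa (signal 237.1), Mst85C (signal 203.8) and bol (signal 127.2) highest. Of 41 developmental homeobox genes, tin and Dll were bound (exact adjusted p = 0.0100). Of 32 antimicrobial peptide genes, Drsl6 alone was bound (exact adjusted p = 0.0102), and this list did not pass in either replicate's own list, where 3 were bound (exact adjusted p = 0.188 and 0.110), in the higher-signal part of the IDR list, or under circular shifts (permutation adjusted p = 0.05003). The testis and homeobox calls were lost in the higher-signal part of the IDR list (odds ratios 0.311 and 0.325). None of 111 replicative histone genes was bound (exact adjusted p = 1.13e-12), but these genes are near-identical repeated copies, so reads cannot be placed among them with certainty.

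Long non-coding RNA and snoRNA genes were bound less often than other genes. Long non-coding RNA genes were bound at 134 of 1959 (6.84%, exact adjusted p = 6.61e-64), the strongest being lncRNA:CR44463, which shares the mRpL41 peak, then lncRNA:CR31044, lncRNA:CR46036 and lncRNA:CR44651. The snoRNA genes were bound at 22 of 269 (exact adjusted p = 7.99e-07), and snoRNA:U49:66Da, among the 4 strongest, shares the RpL14 peak. The snoRNA call was lost at 1000 bp from a TSS (odds ratio 0.865). Of 32 snRNA genes, snRNA:7SKa was bound (exact adjusted p = 0.0331), a call that neither replicate's own list gave (exact adjusted p = 0.390 and 0.258) and that was lost under circular shifts (permutation adjusted p = 0.0651).

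Lists for most adult tissues did not pass. Bound members were 5 of 28 for muscle, 5 of 39 for neurons, 4 of 26 for photoreceptors, 3 of 15 for glia, 9 of 25 for fat body, 6 of 44 for gut digestive enzymes and 1 of 19 for chorion and vitelline genes. Among lists of cell machinery, 11 of 26 heat shock, 12 of 33 vacuolar ATPase, 11 of 32 proteasome, 13 of 44 translation initiation, 23 of 86 oxidative phosphorylation, 11 of 38 cell cycle, 6 of 21 nuclear pore and 4 of 27 spliceosome genes were bound. The others were 12 of 35 glutathione S-transferase, 20 of 85 cytochrome P450, 5 of 24 Notch pathway, 0 of 5 dosage compensation and 45 of 290 tRNA genes. The neuron, gut and tRNA lists passed as depleted in the list of replicate 2 but not in that of replicate 1 (exact adjusted p = 0.0108, 0.0111 and 0.00284).

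**Figure D2:**
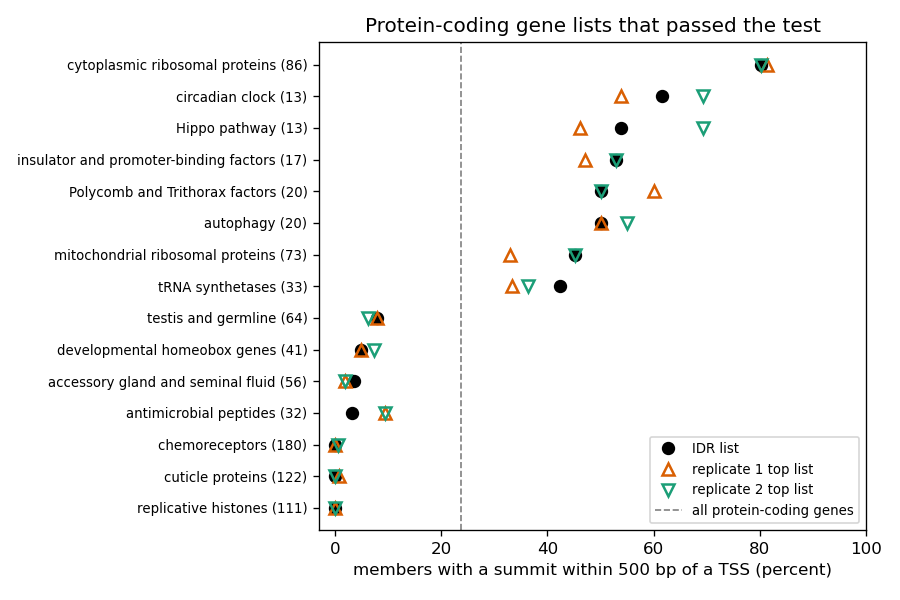
Percent of list members with a summit within 500 bp of a TSS (x axis) for each protein-coding list that passed its test (y axis, number of members in brackets). Filled circles are the IDR list, triangles the top list of each replicate, and the dashed line the 23.8% of all protein-coding genes. Cytoplasmic ribosomal protein genes lie farthest right, at 80.2%.

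Genes with divergent promoters were bound more often. Of 4134 protein-coding genes with a TSS of another gene on the other strand within 500 bp upstream, 1712 were bound (41.4%), against 1602 of 9811 others (16.3%; Fisher's exact test, odds ratio 3.62, p = 7.11e-209). The replicate top lists gave odds ratios of 3.41 and 3.89. Since a summit between paired TSSs counts for both genes, each summit was also given to its nearest TSS only, a choice made after seeing the data, and the odds ratio was then 1.66.

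Promoter summits held particular short sequences more often than unbound promoters of the same GC content. Core promoter motif 7 was found in 461 of 2967 windows (15.5%) against 9.10% of control windows (odds ratio 1.84, exact adjusted p = 1.27e-16). GAGA repeats, the sequence bound by the GAGA factor, were at 2.19% against 0.969% (exact adjusted p = 6.48e-05), and the E-box consensus was at 2.76% against 1.45% (exact adjusted p = 0.000200). The GAGA odds ratio was 2.29, and it was 3.65 in the list of replicate 1 and 2.18 in that of replicate 2. The TATA box was at 5.26% against 7.05% (exact adjusted p = 0.00386). DRE, motif 1, motif 6, BEAF-32 and CTCF consensuses did not pass against unbound promoters. In all, 6 of 19 consensuses were enriched and 3 depleted. The E-box and TATA box calls were lost in the list of replicate 2 (odds ratios 1.29 and 0.814). Both were also lost in the higher-signal part of the IDR list (odds ratios 1.46 and 0.756). The TATA box call was lost again without the mostly soft-masked peaks (odds ratio 0.846). Against flanks of the same summits 9 consensuses were enriched, including 3 of the 6, namely motif 7, GAGA and the E-box. CA repeats, the Zeste consensus and the TCT initiator were not (odds ratios 0.717, 0.977 and 1.09). DRE, motif 1, motif 6, BEAF-32 and the TATA box were more frequent than in those flanks (odds ratios 4.66, 5.67, 3.36, 1.58 and 2.15). Unlike the unbound promoters, the flanks were matched neither on GC content nor on distance from a TSS. Differences from the flanks may therefore reflect either.

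CG33017 summits lay on AT-rich DNA. Mean GC over 50 bp each side of the summit was 35.7%, against 42.9% in flanks 350 to 450 bp away and 42.1% over the main arms. At promoter summits it was 36.2%, against 39.4% in unbound protein-coding promoters at the median offset of those summits. Summit GC was 29.8% in the fifth of the IDR list with the highest signal and 39.1% in the fifth with the lowest. The best 8-mer on 2L and 2R was AATATATT, found on the other arms in 85 of 2920 summit windows (2.91%) against 0.788% of flank windows (Fisher's exact test, odds ratio 3.78, p = 1.53e-13). All 10 best-ranked 8-mers were made of A and T alone. The flanks were not matched on GC content, so base composition alone can make such words more frequent at summits. The 8-mer ranked first differed between lists, being AATATTTA for replicate 2 (odds ratio 2.20) and TATTTTAA for replicate 1 (odds ratio 2.50).

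**Figure D3:**
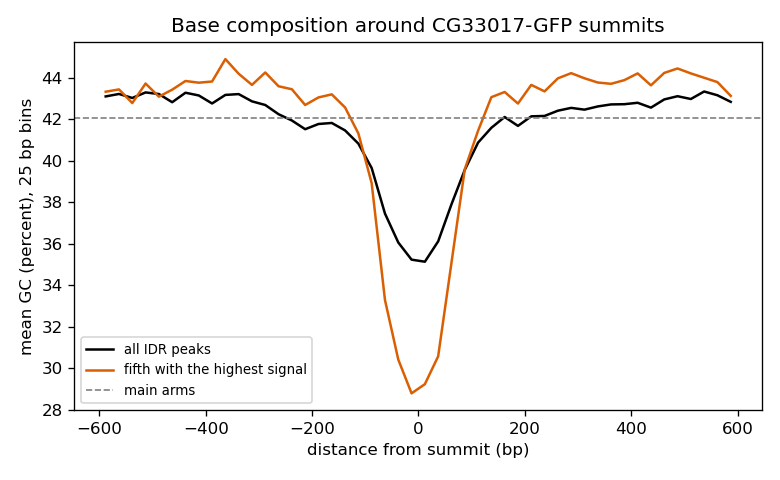
Mean GC in percent in 25 bp bins (y axis) against distance from the summit in bp (x axis), for all IDR peaks and for the fifth with the highest signal. The dashed line is the 42.1% of the main arms, and both curves dip at the summit, more deeply for the strongest peaks.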

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

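Peaks outside the IDR list still favoured promoters. Of the 25133 pooled peaks that the IDR list leaves out, 34.4% (95% interval 33.8 to 35.0%) had a summit within 500 bp of a TSS, 2.54-fold above the 13.6% of bases there. This was singled out because the tests of gene lists, consensuses and 8-mers used only the IDR list and the replicates' top lists. Among the 3000 pooled peaks of lowest signal the promoter share was lower, at 20.3%.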

How the results depend on the processing

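The promoter share, the X to autosome density and the divergent promoter odds ratio kept their direction and passed their test under each alternative run. The promoter share ranged from 50.7 to 71.7%, the X ratio from 0.683 to 0.767 and the divergent odds ratio from 1.66 to 3.89. The best 8-mer passed its test in all 8 settings (odds ratios 1.69 to 3.78) and was made of A and T alone in each. It was 6 different words, so these are not values of a single sequence. The setting without a minimum number of windows gave the main word and value again. Flanks were not matched on GC content, so words of A and T alone can pass from base composition. Recovery of IDR peaks by the replicates was 73.0% when peaks had to overlap by at least 50% of both, 82.2% for summits within 100 bp, 99.9% with all peaks of each replicate and 99.4% for the higher-signal part of the IDR list. With that part alone, 2057 genes were bound and 4 lists enriched, as fewer peaks were used. Enriched lists numbered 4 at 250 bp, 5 at 1000 bp, 3 under circular shifts, 4 with the nearest TSS only (2 kept and 2 gained, heat shock and glutathione S-transferase genes), and 4 to 7 without replicate 1 or 2; the cause was not tested. Cytoplasmic ribosomal protein genes alone were enriched in all 11 settings, and 5 lists were depleted in all 11 (chemoreceptor, cuticle, accessory gland, histone and long non-coding RNA genes). For histone genes this adds little, since no setting changed how reads were placed among their near-identical copies. Against flanks of the same summits, the TATA box (2.15), initiator (1.23) and CA repeat (0.717) odds ratios reversed, and Zeste (0.977) fell just below 1 and lost its call; the cause was not tested. Among named lists, consensuses and classes, another 49 of 246 values lost their call in an unchanged direction. Read depth is unknown here, so it could not be weighed.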

Other observations

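The test of summits without a given 8-mer was chosen after the results were seen. The other tests below were set down before their results were seen, but the patterns had been noticed first in the same data. The design has 1 group, so no biological explanation was tested against another condition.

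Duplicate ribosomal protein genes differed in binding, a comparison chosen after the values were seen. Of 8 pairs of cytoplasmic ribosomal protein genes that the annotation names as a and b copies, 7 had an IDR summit at 1 copy only, and RpL34a and RpL34b were both bound. In 4 of the 7 the same single copy was bound in the top list of each replicate: RpL10Ab (signal 187.6), RpS10b (signal 276.2), RpS19a (signal 189.1) and RpS28b (signal 187.7), with no IDR summit at RpL10Aa, RpS10a, RpS19b or RpS28a. The other 3 pairs were not stable between replicates. RpS15Aa and RpS5a were bound in replicate 2 but not in replicate 1, and of the RpS14 pair replicate 1 had RpS14a and replicate 2 had RpS14b. Copies with near-identical sequence can share reads, and no test of this difference was run.

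GC at the summit fell as signal rose, with Spearman's rho of -0.314 across 4867 IDR peaks. Annotation class did not account for this, since the weaker of the relations within introns and within intergenic sequence was -0.297 (95% bootstrap interval -0.333 to -0.259). Repeat-masked sequence did not account for all of it either, as rho was -0.173 (-0.221 to -0.123) over 1542 windows without a soft-masked base. Bias of the libraries toward AT-rich DNA stays open: unmasked positions at or under 30% GC away from TSSs were inside pooled peaks 1.19 times (1.16 to 1.23) as often as all such positions. That lies between the values set beforehand for excluding it and for favouring it. Binding of the tagged protein to AT-rich DNA would raise the same fold, so this test cannot separate bias from binding. For 64.0% of the IDR peaks the summit was the midpoint of the interval. Whether summits were placed less precisely in weaker peaks was not tested.

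Coding sequence held 0.575% of summits. Random positions matched on GC were coding at 9.09% (95% interval 8.69 to 9.45%), so base composition was not the whole cause. Of summits on unmasked bases 0.746% (0.496 to 1.08%) were coding, against 20.2% of all unmasked bases, which argues against repeats as the cause.

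X held fewer summits than its TSSs predict. The share of divergent promoters did not account for it: it was 27.78% on X and 29.99% on autosomes, and standardising over divergent and other promoters moved the X to autosome ratio of the share of genes bound from 0.628 to 0.638 (95% bootstrap interval 0.576 to 0.698). Other features of promoters were not tested. The single X of males may lower its signal, and this cannot be told apart from lower binding. With X signals doubled, the density ratio was 1.95 (1.83 to 2.08), and a factor of 1.25 brought it to 0.994. If signal scales with copy number, a loss smaller than full copy number would be enough. What the signal measures is unknown here, and the X copy number of the control was not considered, so this scaling was not tested.

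Leaving out windows with 1 fixed 8-base word lowered the share of AT-rich summits only slightly. Of all summit windows 67.9% were AT-richer than their flanks. With the windows that hold AAATATAT left out, the 8-mer of 32470 that lowered this share most, it was 65.9% (95% interval 64.6 to 67.3%) of the other 4575. Sites with variable bases were not covered by this. The part played by the 8-mer ranked first stays open: AATATATT occurred in 1.78 times (95% bootstrap interval 1.41 to 2.20) as many windows as in dinucleotide-shuffled copies of the same windows, and the interval includes the value of 2 set as the bound. A hypothesis that CG33017 carries an AT-hook, a short peptide that binds the minor groove of AT-rich DNA, found no support. Its longest annotated protein, of 1630 amino acids, held 0 copies of the core R-G-R-P, which 0.882% of the 13945 protein-coding genes encode in their longest product.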
